A study of Mus musculus with 8 samples.

How the data were processed

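SNS-seq libraries of CH12 cells were described in the labels as genomic DNA enriched for short nascent strands by size selection and lambda exonuclease digestion, with 4 samples of shLacZ and 4 of shMcm from 2 experiments. The submitters' processing notes name cutadapt 1.4.2, Bowtie 1.0.0, SAMtools, MACS2 2.1.2.1 and bedtools, without a role or an order. Aligner settings, peak thresholds, the control library, the pooling of replicates and the genome build are not given in the sources used here. The authors deposited 2 lists for the whole series, initiation sites and initiation zones, as chromosome, start, end and names, with no read count, score or value per sample, and 0 columns were of unmatched samples. Per the deposited names, each site lists the called peaks it merges, with their knockdown, experiment and peak number but not their replicate, so replicates could not be compared and peaks appear to have been called per knockdown and experiment. Read depth per sample is therefore unknown.

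Samples were grouped by the knockdown given in the labels. The grouping, the descriptions of sites, zones, spacing and X, and the rule for named zones (the 10 with the most sites and the 10 widest) were fixed before the data were examined. The tests of shMcm against shLacZ planned then needed counts per sample, so the comparison by called peaks per window, the overlap test, the denser segments and all of their settings were chosen after the lists were seen. Overlaps with promoters, CpG islands, gene bodies, sequence motifs and gene classes, and the gene names planned for the zones, were not analysed here. The gene table used covers GRCm38, and 448 sites on 10 chromosomes lay beyond its last gene, 200 of them on chromosome 7. The table was therefore taken not to be of the build of the lists. It served only to give the chromosome of named genes and the number of protein coding genes per chromosome. Inside and outside zones could not be compared because 0 sites lay outside.

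Sites were assigned to shLacZ, shMcm or both by the names they carry. Chromosome spans ran from the first base to the end of the last listed site, in place of the sequence without gaps that had been planned. Spacing was compared with 1000 random placements of the same sites on the same chromosome, which could also fall in unsequenced gaps. Overlap of at least 1 bp between shLacZ and shMcm sites was compared with 1000 draws in which each shMcm site was moved at random within 250 kb. Denser segments came from a change-point segmentation of shared sites in 1 Mb windows, with pieces of at least 2 Mb, and were kept at 10 or more shared sites per Mb. Segments were also found from the sites of 1 knockdown alone, with and without the shared sites, at 2 or more times its mean per Mb, to measure the called peaks of the other. The distances joined in zones were read from zones with sites of a single knockdown. Joining shLacZ sites at 16.492 kb and shMcm sites at 13.17 kb rebuilt 17130 and 12208 zones, against highest deposited zone numbers of 17150 and 12229.

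Called peaks per region were recovered from the peak numbers, which rise along the genome in every set. The numbers of the first and last listed peaks around a region bound how many peaks were called in it, on the assumption that numbers run without gaps, and the estimate was interpolated by position between the bounds. Of 539 windows of 5 Mb, 411 were kept, in which every set had at least 10 called peaks and bounds within 50% of the estimate. The 128 windows left out held 6592 shLacZ and 2564 shMcm sites, and 35 of them had no shMcm site and 27 no shLacZ site, so windows nearly empty in 1 knockdown are underrepresented. The median bound was 3.95% and 4.99% of the estimate in shLacZ and 10.9% and 13.1% in shMcm, which is the precision of a window count apart from peak calling. Both experiments of a knockdown were interpolated between the same listed sites. Errors of interpolation can therefore be common to them and differ between knockdowns, and such errors do not enter the spread that the p-values measure. Estimates were scaled to the set's total over the windows, a pseudocount of 1 was added, so that changes of windows with few peaks are slightly understated, and log2 values of 2 shMcm and 2 shLacZ sets were tested with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. No block was used in the main analysis. The experiment numbers in the labels pair the sets, and the deviations of same-numbered sets from their knockdown's mean correlated at 0.48 across windows.

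Correlations between knockdowns across windows were tested by circular shifts of the windows, and correlations across chromosomes by 100000 permutations. The ratio of site numbers was given a 95% Wilson interval, which takes sites as independent and counts shared sites in both numbers. In simulated sets of 411 windows the test recovered 50 of 50 windows changed by 1 log2 unit and 49 of 50 changed by 0.5, called 10 of 311 unchanged windows (3.22%) beside them, and called 0 when no window was changed. The simulated changes were as many up as down, and counts were not recovered from peak numbers. These rates therefore do not cover the effect of scaling or of recovery in the real sets. With shMcm sites moved at random, the overlap test gave a ratio of 0.999. The segmentation found both bounds of a simulated segment in 97 of 100 runs and left 97 of 100 uniform runs in 1 piece. Other window sizes, pseudocounts, bounds, scalings, a replicate block, each peak set left out, other random placements, wider or merged sites and other thresholds for zones and segments were tried as alternatives. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.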

Results

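Short nascent strand sequencing (SNS-seq), which reads the short new DNA strands made where replication starts, was carried out in CH12 cells, a mouse B cell lymphoma line. The 8 samples comprised 4 of a control knockdown labelled shLacZ and 4 of a knockdown labelled shMcm, each from 2 experiments with replicates. Mcm genes encode subunits of the minichromosome maintenance helicase, which is loaded at replication origins and unwinds DNA there, and the labels do not say which subunit was targeted. LacZ is a bacterial gene that mouse cells lack. The title of the series places the data in a study of replication timing and chromosomal translocations, and the comparison implied by the samples is where replication initiates with and without the Mcm knockdown. The deposited lists are named for unstimulated cells, whereas the growth protocol in the labels describes stimulated culture, so the state of the cells is open.

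The deposited lists hold 86459 initiation sites and 21884 initiation zones on 20 chromosomes, as positions without a read count, a score or a sample. Each site carries the names of the called peaks merged into it, which give the knockdown and the experiment but not the replicate, so the measurements below rest on 4 peak sets, 2 per knockdown. The depth of the samples is unknown. If peaks were numbered consecutively, the highest number in each set gives the peaks called: 95033 and 119430 in shLacZ experiments 1 and 2, and 88578 and 134647 in shMcm experiments 1 and 2. In experiment 1 shMcm therefore had fewer called peaks than shLacZ, and in experiment 2 it had more. Nothing in the labels says that the samples came from separate cultures, so p-values measure the spread between these sets, which may be technical. Errors that both sets of a knockdown share are not in that spread. Positions are those of the deposited lists, whose genome build is not given in the sources used here.

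Initiation sites covered 50.3 Mb, at 32.8 sites per Mb of chromosome span, with a median width of 514 bp (range 275 to 8703 bp). Of all sites, 39220 (45.4%) carried peaks of shLacZ only, 30211 (34.9%) of shMcm only and 17028 (19.7%) of both. Their median widths were 447, 517 and 698 bp, and a site of both knockdowns joins more peaks and is wider by construction. Every listed site carried peaks of both experiments of at least 1 knockdown, and 0 sites lay outside a zone. Between 35.7% and 60.2% of the called peaks of a set lay in the listed sites, so the list is a selection of the called peaks. All zones except 1 held more than a single site.

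Initiation zones, the runs of neighbouring sites, covered 408.2 Mb or 15.5% of the chromosome span, with a median width of 12.6 kb (quartiles 6.70 and 21.7 kb) and a median of 3 sites. Zones with sites of shLacZ only numbered 10368, zones with sites of shMcm only 5368 and zones with sites of both 6148 (28.1%). The very largest zones lay on chromosome 15, which held all 10 zones with the most sites and all 10 widest zones, with 9 zones in both lists. Of the 323 zones with at least 20 sites, chromosome 14 held 128, chromosome 15 held 99 and chromosome 16 held 39. The largest ran from 47300099 to 48700016 on chromosome 15, was 1399.92 kb wide and held 441 sites, of which 429 carried shMcm peaks and 151 carried shLacZ peaks. The next zones by sites, also on chromosome 15, ran from 60971058 to 61658977 (229 sites, 211 with shMcm and 158 with shLacZ peaks), from 62299639 to 62856354 (190 sites, 178 and 122) and from 46183004 to 46688856 (148 sites, 144 and 53). All 10 zones with the most sites held more shMcm than shLacZ sites. Whether these zones overlap a gene was not analysed here, because no annotation of their build was used. Zones of a single knockdown joined gaps of up to 16.492 kb in shLacZ and 13.17 kb in shMcm, so zone widths and numbers are not on the same footing in the 2 knockdowns.

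Neighbouring sites of the list lay close together. Of neighbouring pairs, 61.2% were under 10 kb apart, against 39.98% ± 0.120 (SD over 1000 random placements), a ratio of 1.53. The corresponding values were 50.3% against 26.7% for the sites of shLacZ and 64.5% against 33.9% for the sites of shMcm. Because the list holds sites that were joined into zones and the random placements had no such selection, wider random spacing was fixed beforehand, so no p is given and closeness beyond the selection was not tested.

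Chromosomes differed widely in the density of initiation sites. Chromosomes 14, 15 and 16 carried 99.7, 92.6 and 86.7 sites per Mb, and chromosomes 11 and 3 carried 51.7 and 43.7. The median autosome carried 23.4 sites per Mb and the lowest, chromosome 8, carried 18.1. Of the genes set to be named beforehand, the oncogene Myc and its neighbour Pvt1 lie on the dense chromosome 15, whereas the immunoglobulin heavy chain constant region genes Ighm, Ighg1 and Igha lie on chromosome 12 (23.3 sites per Mb), the helicase gene Mcm6 on chromosome 1 (22.8) and the replication timing gene Rif1 on chromosome 2 (23.3). These are averages of whole chromosomes, within which density varied, and no gene position was used. Density at these genes was therefore not measured. The X chromosome carried 86 sites in 26 zones, or 0.517 per Mb, the lowest of the 20 chromosomes (one-sided exact rank p = 0.05, the smallest that 20 chromosomes allow). Of the X sites, 24 lay between 30 and 35 Mb, 19 in the first 5 Mb and 8 in the last 0.1 Mb listed. Called peaks per Mb on X were 0.076 and 0.121 times those of autosomal sequence outside the denser segments described next in shLacZ experiments 1 and 2, and 0.063 and 0.106 times in shMcm, so X was low in all 4 sets before any site was left out of the list.

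**Figure D1:**
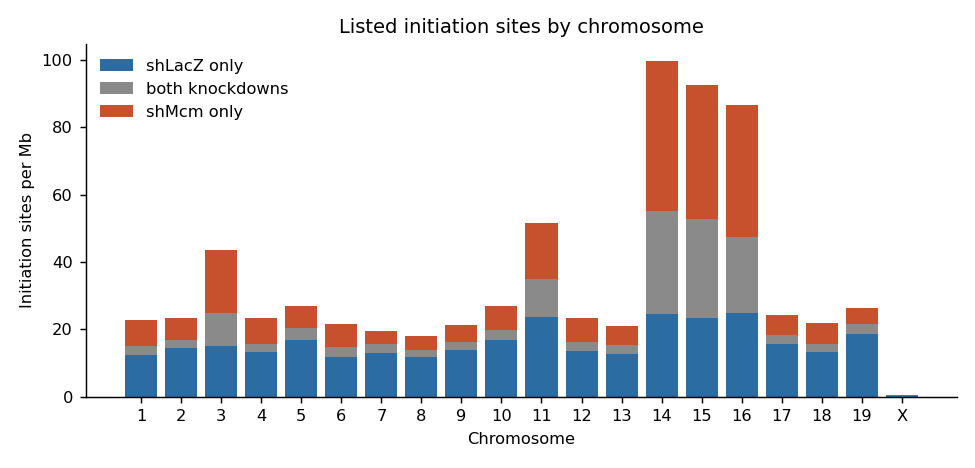
Listed initiation sites per Mb of chromosome span (vertical axis) for each chromosome (horizontal axis), with bars stacked by the knockdown whose peaks a site carries (shLacZ only, both, shMcm only). Chromosomes 14, 15 and 16 stand at 99.7, 92.6 and 86.7 sites per Mb and X at 0.517.

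Initiation sites were concentrated in 11 segments of 6 chromosomes, which together held 42.9% of all sites in 12.5% of the span (329 Mb). They held 36.2% of the shLacZ sites, 59.1% of the shMcm sites and 66.1% of the shared sites that define them. These denser segments, defined as stretches with at least 10 shared sites per Mb, ran from 3 to 8 and 132 to 159 Mb on chromosome 3, 25 to 32 and 50 to 54 Mb on chromosome 7, 3 to 46 Mb on chromosome 11, 21 to 42 and 45 to 125 Mb on chromosome 14, 3 to 19, 39 to 66 and 88 to 103 Mb on chromosome 15, and 14 to 98 Mb on chromosome 16. The densest, from 39 to 66 Mb on chromosome 15, held 192.9 sites per Mb, of which 71.7 per Mb were shared. Those on chromosome 7 were weak. That from 50 to 54 Mb held 33.75 sites per Mb, near the 32.8 of the whole span, with 10 shared per Mb, the limit. That from 25 to 32 Mb held 49.6 sites per Mb, with 11 shared. Both knockdowns were denser inside the segments, which is partly built in because shared sites define the segments and count for each knockdown, shLacZ at 62.0 against 15.5 sites per Mb outside (3.99 times) and shMcm at 84.9 against 8.37 (10.1 times). Of zones with at least 20 sites, 313 of 323 lay inside the segments.

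Called peaks, counted from the peak numbers before sites were selected, were also denser inside these segments in all 4 sets. In shLacZ experiments 1 and 2, called peaks per Mb were 2.62 and 2.39 times those of other autosomal sequence, and in shMcm they were 4.61 and 3.78 times. These ratios are partly built in too, since listed peaks are among the called ones. With segments found from the sites of the other knockdown, shared sites included, they were 2.61 and 2.40 in shLacZ and 4.46 and 3.70 in shMcm, and with shared sites left out 2.42 and 2.23 in shLacZ and 2.21 and 2.01 in shMcm. For called peaks in no listed site the ratios inside the original segments were 1.24 and 1.37 in shLacZ and 1.45 and 1.97 in shMcm. The share of a set's called peaks inside the segments was 28.6% and 26.7% in shLacZ and 41.3% and 36.6% in shMcm, higher in shMcm by 12.8 percentage points in experiment 1 and 9.86 in experiment 2. With 2 sets per knockdown the smallest two-sided exact p is 0.3333, and no other test of this share was run.

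**Figure D2:**
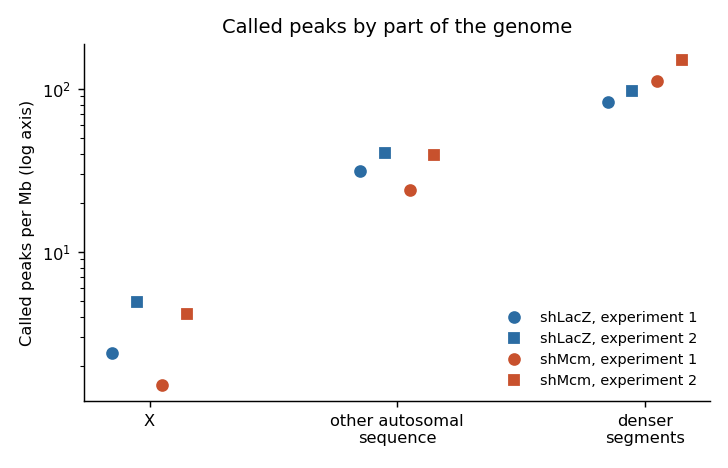
Called peaks per Mb on a log axis for the X chromosome, autosomal sequence outside the denser segments and the denser segments, with 1 point per peak set (colour, knockdown; shape, experiment). In each of the 4 sets X is lowest and the denser segments are highest, at 82.6 and 96.9 peaks per Mb in shLacZ and 111.3 and 149.6 in shMcm.

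**Figure D3:**
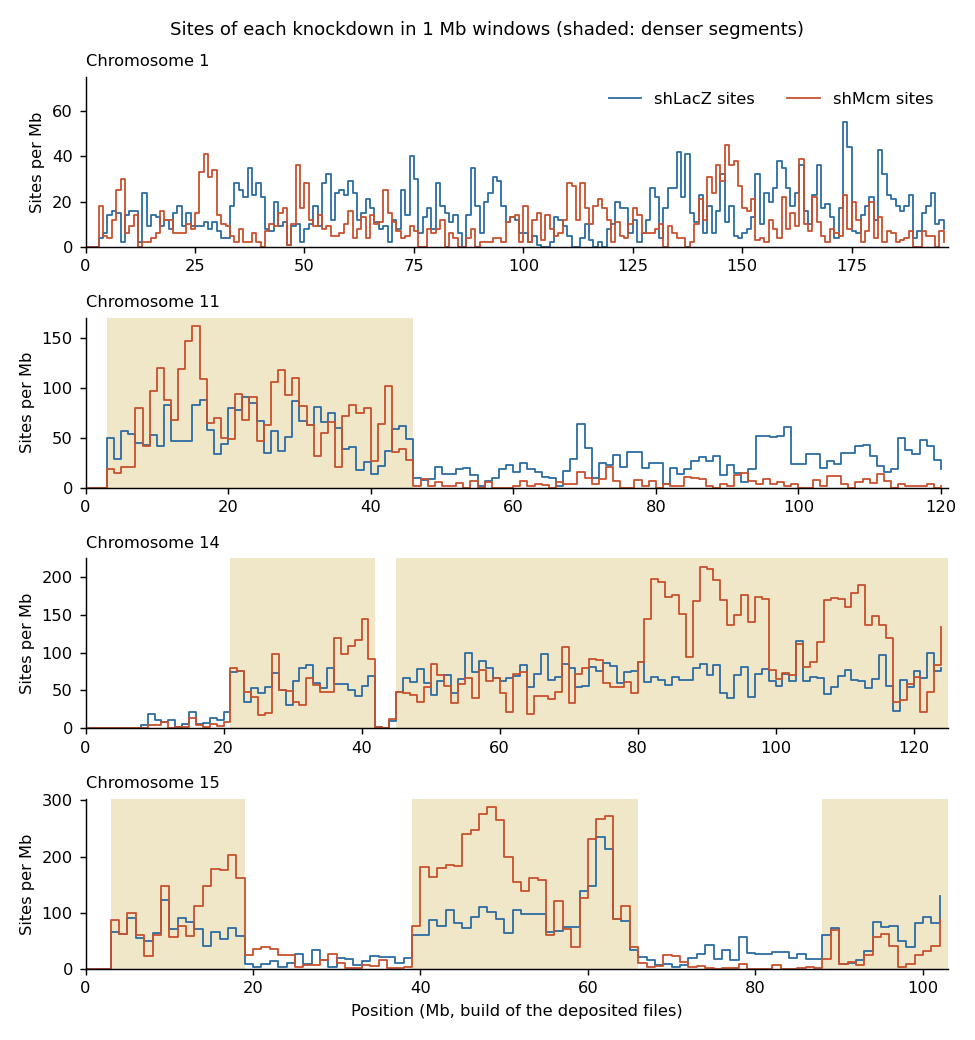
Sites of shLacZ and of shMcm in 1 Mb windows along chromosomes 1, 11, 14 and 15, with position in Mb on the horizontal axis, sites per Mb on the vertical axis (a different scale for each chromosome) and the denser segments shaded. On chromosome 15 the shMcm count reaches 288 sites in the window from 48 Mb, where shLacZ has 102.

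The knockdowns shared a minority of their sites, yet far more than chance placement gives. Sites of shLacZ numbered 56248 and sites of shMcm 47239, a ratio of 1.19 (95% Wilson interval 1.18 to 1.21, meant for counting error only). That interval takes sites as independent and counts shared sites in both numbers, so it is only nominal even for counting error. The 17028 shared sites made up 30.3% of the shLacZ sites and 36.0% of the shMcm sites, against 3249 ± 52.9 (SD) overlaps when shMcm sites were moved at random within 250 kb, a ratio of 5.24 (1000 draws, two-sided permutation p = 0.001, the smallest they can give). Outside the denser segments shLacZ had 1.86 times as many sites as shMcm, and over all 11 of them the ratio turned to 0.73. In 8 segments shMcm had more sites, whereas shLacZ had more from 25 to 32 Mb (334 against 90) and 50 to 54 Mb (127 against 48) on chromosome 7 and from 88 to 103 Mb on chromosome 15 (908 against 494). Of the shMcm sites, 29.8% were shared outside, where random moves gave 1.94% (15.4 times), and 40.3% inside, where they gave 10.3% (3.92 times), in segments that shared sites define. An unshared site is not a site without a peak in the other knockdown, since a peak called there in 1 experiment alone is not listed. Applying the shorter joining distance to both knockdowns lowered the ratio of shLacZ to shMcm sites from 1.19 to 1.08. That ratio could hardly rise, since 47198 of the 47239 shMcm sites already met the distance. For sites of at least the median width the ratio was 0.94, a cut that removes a larger share of the narrower sites of shLacZ only.

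Called peaks were distributed differently between regions in shMcm and shLacZ. Of 411 windows of 5 Mb in which the peaks of all 4 sets could be counted, 111 held a larger share of the called peaks in shMcm than in shLacZ and 200 a smaller share (limma, Benjamini-Hochberg adjusted p under 0.05, 2 sets per knockdown), with a median absolute change of 0.69 on the log2 scale among these 311. Scaling each set to its median window in place of its total gave 180 higher and 149 lower, because the median window fell by 0.28 on the log2 scale when the sets were scaled to their totals. Without any scaling 17 were higher and 20 lower.

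The windows whose share was lowest in shMcm relative to shLacZ lay outside the denser segments on chromosomes 2, 5, 11, 13, 17 and 19. The largest decrease was on chromosome 11 from 115 to 120 Mb (log2 change -2.00, SE 0.10, limma adjusted p = 5.29e-13, or 0.000315 with the experiment number as a block). There 180 sites carried shLacZ peaks only, 10 carried both and 0 carried shMcm peaks only. On chromosome 5 the window from 120 to 125 Mb changed by -1.95 (SE 0.11), that from 140 to 145 Mb by -1.67 (SE 0.11) and that from 115 to 120 Mb by -1.53 (SE 0.10). On chromosome 11 the window from 95 to 100 Mb changed by -1.62 (SE 0.10) and that from 100 to 105 Mb by -1.43 (SE 0.11). The other decreases among the 10 largest were on chromosome 2 from 25 to 30 Mb (-1.48), chromosome 13 from 50 to 55 Mb (-1.45), chromosome 19 from 55 to 60 Mb (-1.41) and chromosome 17 from 45 to 50 Mb (-1.39). None of these 10 windows had bounds within 20% of the estimate in every set, an imprecision that the SE does not include.

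Of the 10 windows with the largest increase in shMcm, 5 lay inside the denser segments and 5 outside. The largest increase was on chromosome 1 from 110 to 115 Mb (log2 change 1.55, SE 0.11, limma adjusted p = 8.06e-11, or 0.000315 with the experiment number as a block), with 13 sites of shLacZ only, 6 of both and 106 of shMcm only. It was followed by chromosome 2 from 95 to 100 Mb (1.26, SE 0.10), chromosome 15 from 15 to 20 Mb (1.23, SE 0.11) and from 45 to 50 Mb (1.22, SE 0.12), and chromosome 14 from 90 to 95 Mb (1.22, SE 0.11). The window on chromosome 15 from 45 to 50 Mb, which contains the largest zone, held 56 sites of shLacZ only, 409 of both and 907 of shMcm only. The rest were chromosome 5 from 80 to 85 Mb (1.19), chromosome 3 from 45 to 50 Mb (1.19), chromosome 14 from 110 to 115 Mb (1.16), chromosome 17 from 90 to 95 Mb (1.12) and chromosome 16 from 65 to 70 Mb (1.12). These 20 windows were picked by size of change after their values were seen, and all 20 kept their direction and stayed past the threshold under both other scalings.

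**Figure D4:**
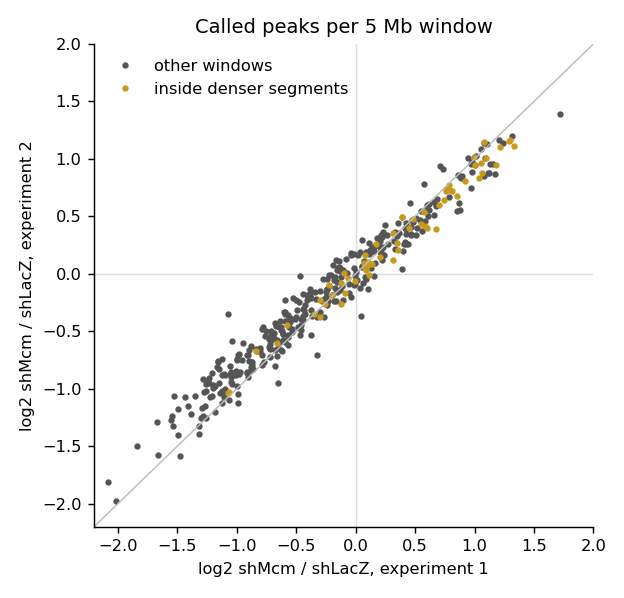
Log2 ratio of shMcm to shLacZ shares of called peaks in each of the 411 windows of 5 Mb, experiment 1 on the horizontal and experiment 2 on the vertical axis, with windows inside the denser segments in yellow and the line of equal values in grey. The points follow the line (r = 0.98) from -2.08 to 1.72 in experiment 1 and from -1.97 to 1.39 in experiment 2.

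Peak sets of the same knockdown resembled each other far more than sets of different knockdowns. Across the 411 windows the log2 shares of the 2 experiments correlated at 0.981 in shLacZ and 0.987 in shMcm, and sets of different knockdowns at 0.560 to 0.606. The change from shLacZ to shMcm measured in experiment 1 correlated with that in experiment 2 at r = 0.98 (rho = 0.98) over all windows, at 0.99 over the 62 windows inside the denser segments and at 0.98 over the 349 outside. Inside the segments 33 windows were higher and 9 lower in shMcm (median log2 change 0.32), and outside 78 were higher and 191 lower (median -0.32). Tested alone, and so relative to their own total, the windows inside gave 20 higher and 30 lower, which turns the majority, and the windows outside gave 123 higher and 160 lower. These correlations run across windows of the same sets, and neighbouring windows are not independent replicates. Counts of both experiments of a knockdown were also interpolated between the same listed sites, which can raise the correlations.

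Regions rich in sites of shLacZ only tended to be poor in sites of shMcm only. Across 424 windows of 5 Mb outside the denser segments the numbers of the 2 kinds correlated at rho = -0.41 (r = -0.41, permutation p by circular shift 0.0024, the smallest 423 shifts can give, Benjamini-Hochberg 0.014 over 6 correlations), and across 62 windows inside at rho = -0.69 (r = -0.66, permutation p 0.016, adjusted 0.036). Counting shared sites on both sides, rho was -0.14 outside (r = -0.11, permutation p 0.024, adjusted 0.036) and 0.34 inside (r = 0.50, permutation p 0.065, adjusted 0.078). Over all 486 windows rho was -0.10 for unshared sites (r = 0.10, permutation p 0.13, adjusted 0.13) and 0.23 for all sites of each knockdown (r = 0.76, permutation p 0.021, adjusted 0.036).

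By whole chromosomes, 14, 16, 15 and 3 held a larger share of called peaks in both shMcm sets than in either shLacZ set. The share of chromosome 14 was 13.1% ± 0.953 (SD, n = 2 sets) in shMcm and 9.36% ± 0.343 in shLacZ, that of chromosome 16 was 9.16% ± 0.431 and 6.63% ± 0.144, that of chromosome 15 was 10.1% ± 1.11 and 7.67% ± 0.388, and that of chromosome 3 was 8.60% ± 0.0614 and 6.94% ± 0.0776. A smaller share in both shMcm sets was found on 13 autosomes, with the largest relative decrease on chromosome 19 (1.63% ± 0.146 against 2.40% ± 0.0182, log2 -0.56), followed by chromosomes 7 (-0.45) and 9 (-0.44). Shares of a set sum to 100%, so a rise on some chromosomes lowers the share of the others, and in experiment 2 chromosomes 4, 6 and 12 of the 13 had more called peaks in shMcm than in shLacZ (6382 against 6019, 6401 against 5934 and 4971 against 4906). On chromosomes 1 and 11 the sets of the 2 knockdowns overlapped, although within experiments chromosome 11 was lower in shMcm both times (6.36% against 6.78% and 5.77% against 6.33%). By chance 33.3% of such splits of 4 sets separate completely, and the smallest two-sided exact p is 0.3333 for each chromosome.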

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

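The settings for zones, for the spacing distance and for zones per Mb were chosen before the data were examined, and all other alternatives, including all for shMcm against shLacZ, were chosen only after the lists were seen. Of 55 alternatives to the main catalogue and comparison results, 37 kept the direction and the side of the threshold where there was a test, stayed within 1.5 times a count, or stayed within the interval (ratio of sites) or quartiles (zone width) of a value without a test. Several of the 37 were fixed in advance or nearly so, such as the spacing ratios, autosomes only (86373 of 86459 sites) and zones without the widest 1% (21665 of 21884). The tally therefore says little about robustness. Spacing ratios, whose direction the selection of sites fixed, lay between 1.33 and 2.29, shared sites between 3.92 and 15.4 times random, and denser segments between 305 and 344 Mb, and X ranked lowest under each density tried (zones, shLacZ sites and shMcm sites per Mb). The 20 named windows kept their direction and side in all 188 alternatives that could test them. With bounds within 20% none of the named decreases was left to test. Nor were the increases on chromosome 2 from 95 to 100 Mb and chromosome 5 from 80 to 85 Mb. The counts of these windows are therefore less precise. The unknown read depth, the recovered rather than counted peaks and 2 sets per knockdown limit the window test.

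By construction, fewer features were left by sites of at least the median width (43261) and by zones with at least 5 sites (4289, median width 37.1 kb). The ratio of shLacZ to shMcm sites, 1.19, was 1.08 with the shorter joining distance for both knockdowns and 1.86 outside the denser segments. It reversed to 0.73 inside them and to 0.94 for sites of at least the median width of 514 bp. Sites of shLacZ only had a median width of 447 bp and sites of shMcm only 517 bp, so that cut removes a larger share of the former. Why the widths differ was not tested. Windows higher and lower in shMcm, 111 and 200, numbered 190 and 306 at 2 Mb and 61 and 103 at 10 Mb, where more or fewer windows exist. They numbered 68 and 113 with bounds within 20%, where 260 windows were tested, and 20 and 30 when windows inside the denser segments were tested alone, where the majority of higher windows there (33 against 9) turned, since each set is then scaled to its total inside. Scaling to the median window gave 180 higher and 149 lower. No scaling gave 17 and 20, since the totals of the 2 experiments then add to the spread. With 1 peak set left out, which assumes that a lone set varies like the pair, counts ranged from 86 to 121 higher and from 173 to 205 lower. With the experiment number as a replicate block, 123 windows were higher and 208 lower, and all 311 calls made without it were kept. Not run were the alternatives for promoters, CpG islands, gene bodies, motifs and gene classes, spacing outside CpG islands, density in non-repeat sequence, sites inside against outside zones, and the tools and filters for counts per sample.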

Other observations

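The tests of the joining distance and of gene density were chosen after the lists but before their own results were seen, and all other tests here were chosen only after the pattern was seen.

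Chromosomes with fewer protein coding genes tended to hold a larger share of called peaks in shMcm. Over the 19 autosomes the log2 change in share correlated with protein coding genes per Mb at r = -0.50 (permutation p = 0.0291, Benjamini-Hochberg 0.0291 over 2 relations) and rho = -0.58 (permutation p = 0.00961), and without chromosomes 7 and 11, the farthest in gene density, at r = -0.54 (permutation p = 0.0238). Over the 13 autosomes without a denser segment r was -0.68 (permutation p = 0.0103, adjusted 0.0206) and rho -0.59 (permutation p = 0.0356), but without chromosomes 17 and 19 r was -0.48 (permutation p = 0.136), so there the relation was weaker and no longer passed 0.05. Gene counts came from GRCm38, taken to be another build than that of the lists. A hypothesis is that initiation after Mcm knockdown may shift towards gene-poor, often late replicating, regions. Chromosomes are few and differ in many other ways, so these values leave it open.

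Sites within a zone lay closer together in shMcm than in shLacZ, with a median gap of 4.13 kb against 6.157 kb. Inside the denser segments the medians were 3.5055 and 5.5485 kb, and outside 5.612 and 6.6 kb. Zones joined shorter gaps in shMcm, which lowers its median by construction, and no test was run. In 107 of the 6148 zones with sites of both knockdowns, no site was shared.

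The first pattern to weigh is the denser segments, with 42.9% of all sites in 12.5% of the span. The selection of reproducible, clustered sites is argued against as the whole cause. In segments found from sites of the other knockdown only, shared sites left out, called peaks were at least 2.01 times as dense as in other autosomal sequence in every set. But peaks in no listed site were only 1.24 to 1.97 times as dense inside the original segments. Those segments held 36.2% of the shLacZ sites against 28.6% and 26.7% of the called peaks in experiments 1 and 2. For shMcm they held 59.1% of the sites against 41.3% and 36.6% of the called peaks. The contrast is therefore larger in the list than among called peaks, though listed shared sites define the segments. How much of it comes from the selection stays open. A response seen only with the Mcm knockdown is argued against by the lower of the shLacZ values in segments found from sites of shMcm only, 2.23. Extra copies of these segments in this line could raise the number of peaks called there. Called peaks per Mb were higher in the denser segments than in other autosomal sequence in 4 of 4 sets, which this explanation needs. Others, and in part the choice of the segments, would give that too. X was lowest in 4 of 4 sets, but extra copies of the segments require nothing of X. With no copy numbers analysed here, that explanation stays open beside a true concentration of initiation, which was not tested.

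A second pattern is the regional difference between knockdowns. A different number of called peaks is argued against, since shMcm had fewer than shLacZ in experiment 1 and more in experiment 2 while the changes of the 2 experiments correlated at 0.98. The denser segments alone are argued against as well, since the changes also varied between windows outside them. There the log2 change averaged over both experiments had an SD of 0.662 between windows. That was 8.34 times the SD of an experiment's deviation from this average, 0.0793. Such a deviation is smaller than the difference between the experiments. Weaker enrichment of nascent strands in the shMcm libraries could move called peaks towards segments with more DNA copies, but the higher share of shMcm peaks inside the denser segments, by 12.8 and 9.86 percentage points in experiments 1 and 2, is what prompted this explanation and does not test it. As worded, the enrichment account concerns only the segments as a whole. Outside them 78 windows were higher in shMcm and 191 lower, and inside 33 were higher and 9 lower. Whether weaker enrichment could also shift such windows was not tested, since neither enrichment nor copy number was measured here. A changed use of origins after Mcm knockdown could also raise the share inside. Enrichment and origin use cannot be told apart with these lists.

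The smaller number of sites in shMcm is a further pattern, and part of it may come from how zones were built. With the shorter joining distance for both knockdowns the ratio of shLacZ to shMcm sites was 1.08, against 1.19 in the lists, a value between the bounds set beforehand for and against the distance as the cause, so it stays open. Nearly all shMcm sites already met that distance (47198 of 47239), so the ratio could hardly rise whatever the cause. The ratio was 1.86 outside the denser segments and 0.73 inside them, so the total combines opposite differences, although in 3 of the 11 segments, both on chromosome 7 and that from 88 to 103 Mb on chromosome 15, shLacZ had more sites. For sites of at least the median width the ratio reversed to 0.94, a cut that removes a larger share of the narrower sites of shLacZ only. An effect of the Mcm knockdown itself also stays open.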
